A study of Danio rerio with 16 samples.

How the data were processed

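The series holds 16 RNA samples of whole zebrafish larvae in 4 groups of 4, hybridised on 16 arrays of a custom 60-base oligonucleotide design, 4 arrays to a slide. Per the labels, RNA of 20 larvae per sample was amplified with amino allyl nucleotides and coupled to Cy3 or Cy5. The reference was mixed from all RNA samples of the study. The deposited scanner files give the intensity of each spot and of its local background in both channels, per the file headers made with Agilent Feature Extraction 10.7.3.1. The submitters' processing notes name versions 9.5.3.1 and 9.5 instead. The deposited files also hold processed signals, which per the file headers were detrended and dye-normalized with LOWESS settings, with background correction off, and the log10 ratio of red over green made from them. The authors' deposited file of normalized values equals that log10 ratio: its columns correlated with the scanner ratio of their own array at 0.999999, against at most 0.678 with any other array. Its column medians lay between -0.0104 and 0, no further centring was found, and its direction is the scanner's red over green. The genome build in the headers, danRer5, is the platform's, and no probe carries coordinates.

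Samples were grouped by their titles and channel 2 source names. One con/veh sample has a description that names another group, and its title was followed. The labels speak of individual experiments, so the 4 samples of a group were taken as separate batches of larvae. In the labels, replicates 1 to 3 have the same experiment code in all groups, while replicate 4 has code 5 in the vehicle samples and code 4 in the beclomethasone samples. The replicate number was taken to pair the samples, because it marks a shared slide and, for replicates 1 to 3, a shared experiment in all groups. In replicate 4 the comparisons of beclomethasone with vehicle pair samples of codes 4 and 5. The deviations of same-numbered samples from their group means correlated, across probes, between 0.0989 and 0.374 for replicate 1, 0.392 and 0.571 for replicate 2, -0.22 and 0.475 for replicate 3, and 0.139 and 0.664 for replicate 4. Of the 16 arrays, 14 correlated best with an array of their own number. Replicate number, slide and scan coincide and cannot be separated.

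Mean spot signals were corrected with limma's normexp method (offset 50, local median background) and normalized by loess within each array. Control spots (4848 of 180822 per array) had weight 0 in the loess and were then left out, as were spots with an outlier flag. Each of the 175974 remaining probes had 1 spot. The design fixed before the data were examined took the sample as Cy5 over Cy3, as labelled. The signals contradicted this, as the results describe, and all ratios were turned to green over red and the filter applied to the green channel. The design also averaged the probes of a gene, but the files name no gene, so each probe was tested by itself. Probes were kept when well above background in green on all 4 arrays of at least 1 group (145246 probes), and tested when each group had at least 3 values (145023). On all 16 arrays 132910 probes were above background.

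A linear model with 4 group means was fitted to the log2 ratios of all 16 arrays with limma (lmFit and eBayes), so that every comparison used 1 estimate of the spread. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested probes of each comparison, with a threshold of 0.05. The comparisons were amputation in vehicle, amputation under beclomethasone, beclomethasone in intact larvae, beclomethasone in amputated larvae, and the interaction. No statistical model is stated in the labels, so the block for the replicate number was an alternative, and its counts are printed where they differ by more than 1.5 times. Probes that share at least 30 bases in a row on the same strand were joined into groups, and counts of groups are given beside counts of probes. Tested probes of the same strand that overlap (7737 pairs) had log2 changes that correlated between 0.853 and 0.944 over the 4 comparisons, with 0 pairs called in opposite directions. Scores of single arrays were compared by exact permutation of 4 against 4 arrays.

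The probes named in the text followed a rule fixed before the data were examined: the largest rises and falls among probes past the threshold with the same sign in all 4 same-numbered pairs. The rule also asked for a gene symbol, which no probe has, and that part was dropped. The rule asked for 8 of each, and the first 2 of each per comparison are named. The 28 gene lists and the 3 single genes fixed with it could not be used for the same reason, and their tests were not run. The named probes were well above background on all arrays of every group.

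The steps were tested on simulated data made from these arrays, with 50 probes for each of 4 sizes of change, before they were run. For amputation in vehicle, 16% of probes with a log2 change of 0.5, 82% of those with 1 and 100% of those with 2 were found. These shares hold for data with that many changed probes and with noise drawn independently for each probe. Alternatives covered the block, the background correction, the normalization, the filter, the deposited values, the arrays in the fit, array quality weights, a 2-fold minimum, and leaving out each array and each slide. Added after seeing the data were the removal of a trend on probe GC content (smoothing spline, 6 degrees of freedom), the removal of the arrays that stood apart, the green channel alone, 1 probe per overlap group, and red as the sample channel. R 4.3.3, limma 3.58.1, data.table version 1.17.8 and statmod 1.5.0 were used for the statistics, and Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 for probe overlaps and figures.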

Results

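Transcript levels were measured in whole zebrafish larvae at 3 days post fertilization (dpf), to compare the response to a wound with and without a glucocorticoid. The tail fin was amputated or left intact, and larvae were kept in 25 µM beclomethasone, a synthetic glucocorticoid, or in vehicle (0.05% dimethyl sulfoxide, the solvent). Treatment began 2 h before amputation and lasted until collection 4 h after it. The 4 groups are called con/veh, amp/veh, con/beclo and amp/beclo, with con for intact and amp for amputated larvae. Each group held 4 samples, each of 20 pooled larvae, and each sample shared an array with a common reference made from all RNA samples. Every slide carried 1 sample of each group, and the replicate number of a sample was also its slide and scan. Between 81.3 and 88.6% of the 175974 probes per array were well above background in the green channel, and no spot was saturated. The number of arrays limits the precision of every value. The files pair 0 probes with a gene name, so probes are given by their ID and 60-base sequence, and nothing is said of the genes behind them. Of the probes, 145023 were tested, and they fell into 129788 groups of overlapping sequence.

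The direction of each ratio was taken from the signals, because they contradicted the labels. The labels give the larval samples Cy5, the red dye, but the name they give for the dye of the reference differs for the samples of replicate 4. Among the 1000 probes whose ratio varied most, the median SD over the 16 arrays was 0.997 in log2 green signal and 0.0958 in log2 red signal. Over the same probes, the mean of the 16 green-over-red ratios had a median log2 of 0.06 (quartiles -0.12 and 0.22), near the 0 that a reference mixed from all samples gives. For red over green the median was 0.60 (quartiles 0.38 and 0.90). The larval samples are therefore likely to be in the green channel and the reference in the red one, and every change below is green over red. This is opposite to the direction that the labelled dyes give, under which each rise below is a fall and each fall a rise. With red as the sample channel for filter and sign, 900 probes rose and 600 fell with beclomethasone in intact larvae, 1427 rose and 460 fell with it in amputated larvae, 341 rose and 15 fell with amputation under beclomethasone, and 1 rose with amputation in vehicle. Groups are named as labelled throughout.

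**Figure D1:**
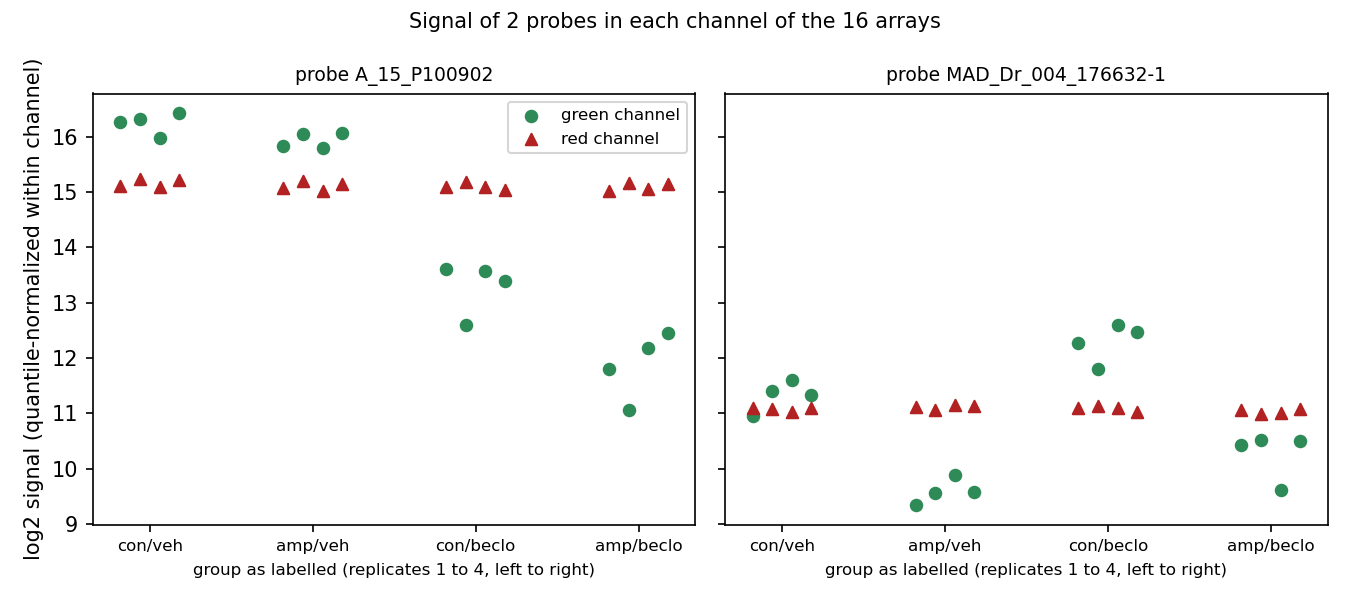
Log2 signal of probes A_15_P100902 and MAD_Dr_004_176632-1 in the green (circles) and red (triangles) channel of the 16 arrays, by group as labelled, quantile-normalized within each channel. For A_15_P100902 the SD over the 16 arrays was 1.92 in green and 0.07 in red, and for MAD_Dr_004_176632-1 it was 1.10 in green and 0.05 in red.

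The first comparison asked which transcripts amputation altered in vehicle-treated larvae. A single probe changed, MAD_Dr_004_176632-1 (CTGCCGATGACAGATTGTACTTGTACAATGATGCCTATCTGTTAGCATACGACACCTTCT), which was 3.39-fold lower in amp/veh than in con/veh. Its mean log2 ratio to the reference was 0.10 ± 0.30 (SD, n = 4) in con/veh and -1.66 ± 0.21 in amp/veh, a log2 change of -1.76 ± 0.21 (SE), lower in 4 of 4 same-slide pairs (limma adjusted p = 0.032). With the replicate number as a block this probe had an adjusted p of 0.0506, and another probe, LOLT00573, named here because it was the single call of that fit, fell by 1.89 on the log2 scale (adjusted p = 0.0109). At an unadjusted p under 0.05 there were 3417 probes, against 7251 expected by chance alone. A count under chance means that these p-values were not evenly spread, and it does not show that amputation had no effect. On simulated data made from these arrays, the same test found 82% of probes changed by a log2 of 1 and 16% of those changed by 0.5. The simulation changed many probes at once, which makes the adjusted threshold easier to pass, and drew its noise independently for each probe. With 1 call in the real comparison, these shares are likely too high for it, and they do not show that larger changes were absent. The amp/veh replicate 1 array had an SD of log2 ratios of 0.526, against 0.311 to 0.320 in the other 3 arrays of its group, and without it 0 probes were called. The count was also 0 without amp/veh replicate 2, 3 or 4, con/veh replicate 2, 3 or 4, con/beclo replicate 1 or 4, or amp/beclo replicate 1 or 4. The scanner software's own log ratios also gave 0 called probes, and a fit of the con/veh and amp/veh arrays alone gave 8, all lower.

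Under beclomethasone, amputation changed 364 probes, of which 15 rose and 349 fell, in 299 groups of overlapping sequence. The median log2 change was 0.57 among the rises, and 0.99 in size over all 364 probes, and 1 rise and 177 falls were at least 2-fold (1 and 361 with the replicate block, 3 and 110 with the scanner's processed signals). The largest falls were LOL04917 (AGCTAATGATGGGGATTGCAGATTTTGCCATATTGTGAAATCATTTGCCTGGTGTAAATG), 9.66-fold lower in amp/beclo than in con/beclo, and MAD_Dr_004_170500-1 (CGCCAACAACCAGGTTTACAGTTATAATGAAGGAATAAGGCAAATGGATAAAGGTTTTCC), 8.81-fold lower. For LOL04917 the mean log2 ratio was 0.96 ± 1.07 (SD, n = 4) in con/beclo and -2.31 ± 1.17 in amp/beclo (log2 change -3.27 ± 0.49 SE, limma adjusted p = 0.011). The SE and p rest on 1 spread over all 4 groups, and its SD was smaller in con/veh (0.28) and amp/veh (0.23). They therefore understate the spread of the 2 groups compared. The same holds for MAD_Dr_004_170500-1, with SDs of 1.52 in con/beclo, 0.98 in amp/beclo, 0.43 in con/veh and 0.81 in amp/veh. The log2 change of MAD_Dr_004_170500-1 was -3.14 ± 0.61 (adjusted p = 0.0395), a call that was lost with the scanner's processed signals (0.0909), the authors' deposited values (0.0913), array quality weights (0.0541), the GC correction (0.0615), the arrays that stood apart left out (0.0791) and a fit of the 2 groups alone (0.199). The largest rises were smaller. MAD_Dr_004_640980-1 (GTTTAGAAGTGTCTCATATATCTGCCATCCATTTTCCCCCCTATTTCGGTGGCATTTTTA) rose 2.42-fold, from -0.69 ± 0.28 (SD, n = 4) to 0.58 ± 0.50 (log2 change 1.27 ± 0.21 SE, adjusted p = 0.0155), and LOLS15693 (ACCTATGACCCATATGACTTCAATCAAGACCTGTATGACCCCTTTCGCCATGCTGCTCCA) rose 1.94-fold (log2 change 0.96 ± 0.15 SE, adjusted p = 0.0136). In vehicle each of these named probes changed the same way in 4 of 4 same-slide pairs, none past the threshold in the main fit. A fit of the con/veh and amp/veh arrays alone did call LOL04917 (limma adjusted p = 0.00792). The log2 changes in vehicle were -1.82 for LOL04917, -1.07 for MAD_Dr_004_170500-1, 0.91 for MAD_Dr_004_640980-1 and 0.72 for LOLS15693. Beclomethasone raised LOL04917 in intact larvae by a log2 of 2.15 (limma adjusted p = 0.0416). That rise and its fall use the same con/beclo arrays and are not independent. All 364 probes changed the same way in 4 of 4 same-slide pairs. With the replicate block 150 probes rose and 1115 fell, and the 364 were all among them. A fit of the con/beclo and amp/beclo arrays alone called 0 probes, the scanner's log ratios gave 10 rises and 122 falls, and leaving out slide 3 left 3 falls.

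The labels ask how the glucocorticoid altered the changes that amputation made. The 1 probe that fell in vehicle, MAD_Dr_004_176632-1, also fell under beclomethasone, by 1.98 on the log2 scale, and its interaction was -0.22 ± 0.30 (SE, unadjusted p = 0.471). The probes selected under beclomethasone changed less in vehicle: the median ratio of their change in vehicle to that under beclomethasone was 0.41, and 98.9% of the 349 falls went the same way. Selection makes a change too large in the arm it was made in, so probes were also selected on 2 replicate numbers and measured in the other 2, in all 6 splits. For the 100 probes with the smallest p under beclomethasone, the change in the unused replicates was 2.37 times as large under beclomethasone as in vehicle (range over the splits 1.59 to 3.19). For the 100 selected in vehicle it was 1.87 times as large under beclomethasone (range 1.37 to 2.49). This second ratio was smaller without the arrays that stood apart, 1.40 without amp/veh replicate 1 and 1.26 without amp/veh replicate 1 and amp/beclo replicate 3 (1.19 with the replicate block as well), and it was 2.84 without amp/veh replicate 4. The first was 3.45 without con/beclo replicate 4. Neither ratio tells whether the level of the intact or of the amputated larvae made the difference. As labelled, the mean change over the splits was larger under beclomethasone in both selections and in every setting run, but single splits fell below 1. For the selection in vehicle, 1 of 6 splits did so with the arrays that stood apart left out and the replicate block (0.92), and without con/beclo replicate 1 (0.61), amp/veh replicate 1 (0.99), con/veh replicate 3 (0.28), amp/veh replicate 4 (0.94), amp/beclo replicate 4 (0.86) or con/veh replicate 4 (0.93). For the selection under beclomethasone, 1 of 6 did so without con/beclo replicate 1 (0.94) or amp/beclo replicate 4 (0.81). The interaction passed the threshold for 0 of the 145023 probes (limma), with 2686 at an unadjusted p under 0.05 and 7251 expected by chance, and with the replicate block it was also 0. A count under chance does not show that interactions were absent. The test found 46% of simulated interactions of log2 1 and 96% of those of log2 2. Many probes were changed at once in that simulation, so these shares are likely too high for a comparison with 0 calls. Adjusted over the 364 probes alone, 159 had an interaction, none opposite to its change, but this count is not independent of how the probes were chosen.

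**Figure D2:**
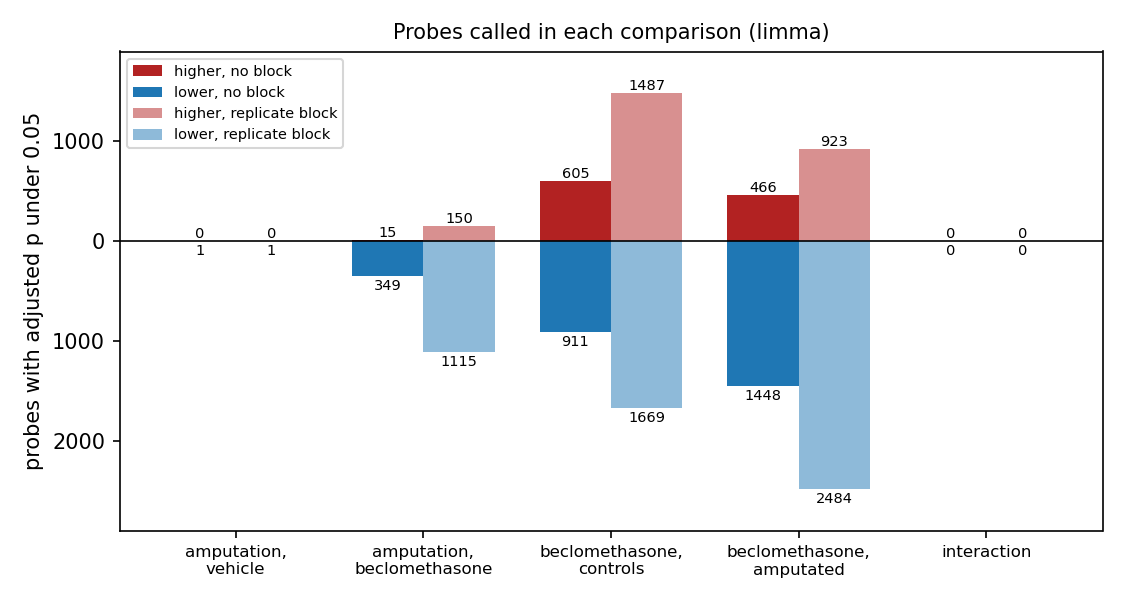
Number of probes higher (above 0) and lower (below 0) in each comparison at a Benjamini-Hochberg adjusted p under 0.05, without a block (full colour) and with the replicate number as a block (pale). Amputation gave 0 rises and 1 fall in vehicle and 15 rises and 349 falls under beclomethasone, and beclomethasone gave 605 rises and 911 falls in intact and 466 rises and 1448 falls in amputated larvae.

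In intact larvae, beclomethasone changed 1516 probes, of which 605 rose and 911 fell, in 1333 groups of overlapping sequence. The median log2 change was 0.67 among the rises and -0.84 among the falls, and 97 rises and 295 falls were at least 2-fold (207 and 379 with the replicate block, 128 and 424 with the scanner's processed signals). The largest falls were MAD_Dr_004_156566-1 (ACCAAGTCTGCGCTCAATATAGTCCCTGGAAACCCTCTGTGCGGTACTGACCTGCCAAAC), 8.89-fold lower in con/beclo than in con/veh, and MAD_Dr_004_198806-1 (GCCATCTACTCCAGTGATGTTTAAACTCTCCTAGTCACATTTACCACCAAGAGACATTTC), 8.81-fold lower. For MAD_Dr_004_156566-1 the mean log2 ratio was 0.90 ± 0.70 (SD, n = 4) in con/veh and -2.25 ± 0.70 in con/beclo (log2 change -3.15 ± 0.51 SE, limma adjusted p = 0.00411), and MAD_Dr_004_198806-1 changed by -3.14 ± 0.47 (adjusted p = 0.00207). The largest rises were MAD_Dr_004_170500-1, 6.23-fold (log2 change 2.64 ± 0.61 SE, adjusted p = 0.0452), and LOL02517 (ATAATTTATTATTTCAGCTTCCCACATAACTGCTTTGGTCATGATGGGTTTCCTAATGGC), 5.08-fold (log2 change 2.34 ± 0.55, adjusted p = 0.0484). The level of MAD_Dr_004_170500-1 went from -1.16 ± 0.43 (SD, n = 4) in con/veh to 1.48 ± 1.52 in con/beclo, where single arrays ran from -0.43 to 3.30. The same con/beclo arrays enter its fall after amputation under beclomethasone, so the rise and the fall are not independent. Both rises lay near the threshold. For MAD_Dr_004_170500-1 and LOL02517 the adjusted p was 0.0531 and 0.0565 with no probe filter, 0.0994 and 0.0847 with the scanner's processed signals, and 0.0577 and 0.0613 in a fit of the con/veh and con/beclo arrays alone. Both calls were lost on leaving out any single array except con/beclo replicate 4, amp/veh replicate 1 or amp/beclo replicate 1, with an adjusted p up to 0.156 and 0.179, both without con/veh replicate 4. Of the 1516 probes, 1509 changed the same way in 4 of 4 same-slide pairs. With the replicate block 1487 rose and 1669 fell, and all 1516 were among them. Which direction held more probes moved with the scaling. Median centring in place of loess gave 810 rises and 687 falls, the scanner's processed signals gave 299 and 718, and the authors' deposited values gave 299 and 716. Without con/beclo replicate 4 there were 725 rises and 720 falls.

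In amputated larvae, beclomethasone changed 1914 probes, of which 466 rose and 1448 fell, in 1645 groups of overlapping sequence. The median log2 change was 0.65 among the rises and -0.90 among the falls, and 16 rises and 621 falls were at least 2-fold (21 and 742 with the replicate block, 68 and 804 with the scanner's processed signals, 70 and 806 with the authors' deposited values). The largest falls of any comparison were here. MAD_Dr_004_148407-1 (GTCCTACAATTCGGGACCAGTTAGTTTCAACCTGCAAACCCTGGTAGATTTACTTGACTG) was 19.1-fold lower in amp/beclo than in amp/veh, from 1.33 ± 0.47 (SD, n = 4) to -2.92 ± 0.84 (log2 change -4.25 ± 0.35 SE, limma adjusted p = 4.26e-06). A_15_P100902 (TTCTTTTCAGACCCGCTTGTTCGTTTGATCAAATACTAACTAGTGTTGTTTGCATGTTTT) was 18.8-fold lower (log2 change -4.23 ± 0.27, adjusted p = 7.55e-07). Both also fell with beclomethasone in intact larvae (log2 changes -2.98 and -2.99). The largest rises were MAD_Dr_004_711827-1 (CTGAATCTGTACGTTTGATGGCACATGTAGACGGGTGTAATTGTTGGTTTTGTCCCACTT), 4.30-fold (log2 change 2.11 ± 0.36 SE, adjusted p = 0.00426), and MAD_Dr_004_158535-1 (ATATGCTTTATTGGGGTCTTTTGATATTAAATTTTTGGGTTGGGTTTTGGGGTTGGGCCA), 3.73-fold (log2 change 1.90 ± 0.26, adjusted p = 0.000565). MAD_Dr_004_711827-1 also rose in intact larvae, by a log2 of 1.67, as did MAD_Dr_004_158535-1, by 1.37. Of the 1914 probes, 1887 changed the same way in 4 of 4 same-slide pairs. With the replicate block 923 rose and 2484 fell, and 1911 of the 1914 were among them. A fit of the amp/veh and amp/beclo arrays alone called 105 rises and 766 falls, and MAD_Dr_004_711827-1 was no longer called (adjusted p 0.0722).

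**Figure D3:**
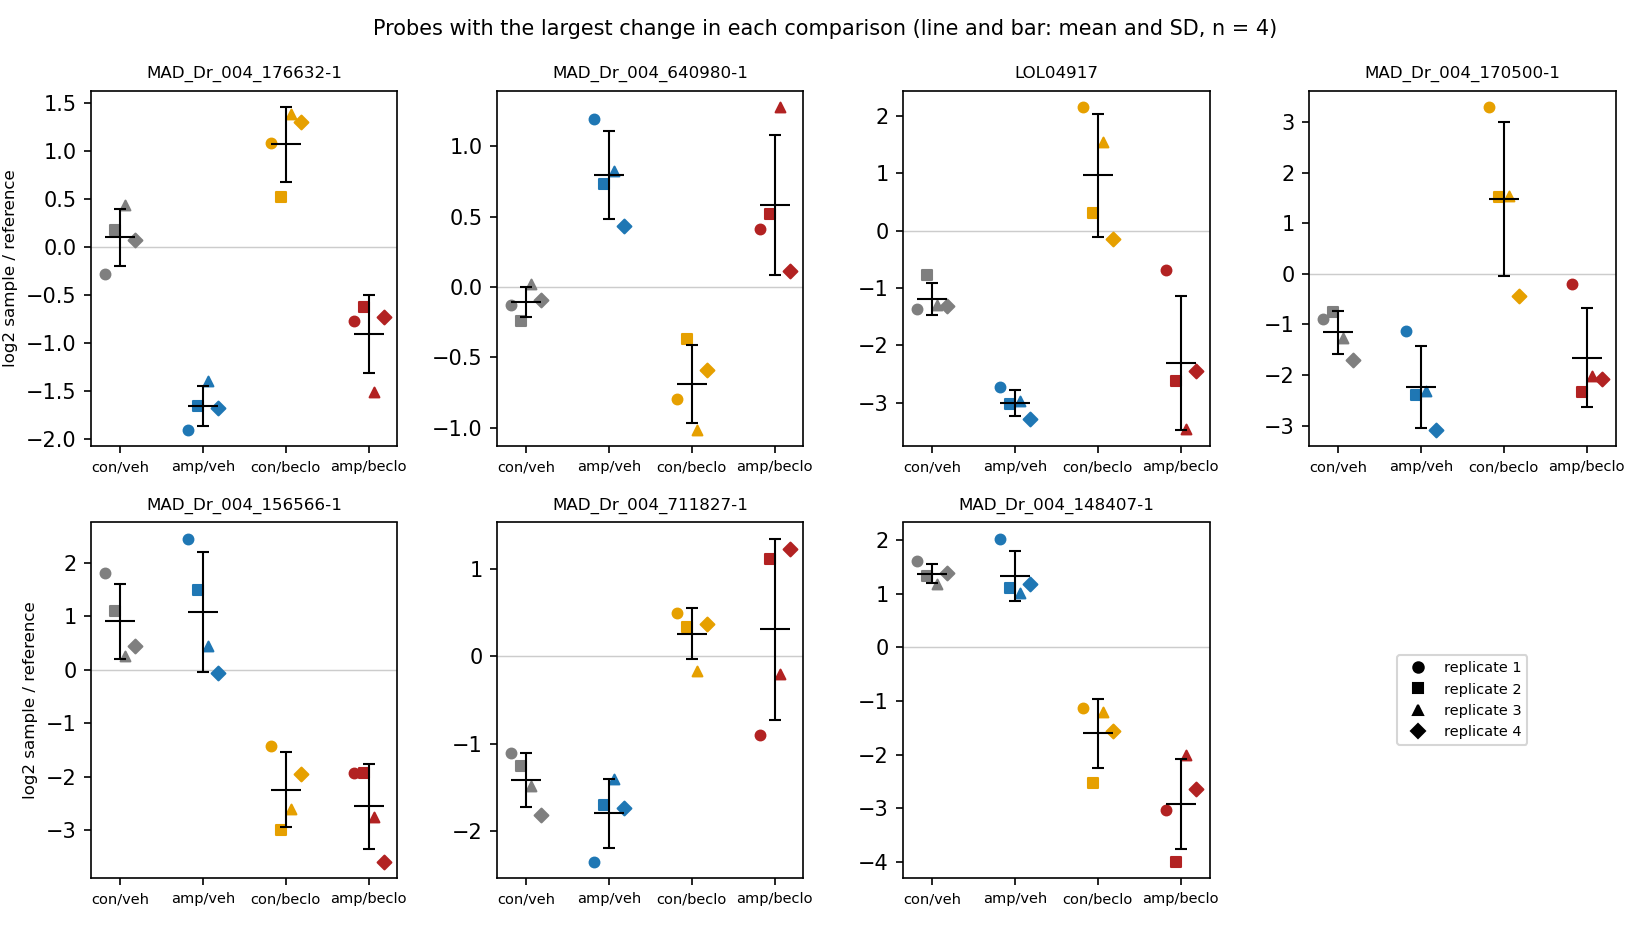
Log2 ratio of larval sample to common reference for 7 probes with the largest rise or fall in a comparison, by group as labelled (symbols, replicates 1 to 4; line and bar, mean and SD, n = 4). MAD_Dr_004_148407-1 lay at 1.38 in con/veh and 1.33 in amp/veh on average, and at -1.60 in con/beclo and -2.92 in amp/beclo.

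The comparisons of beclomethasone in intact and in amputated larvae compared different arrays, with 1 shared estimate of the spread, and called 992 probes in common, 258 that rose and 734 that fell. Independent lists of these lengths would share 1.94 and 9.10 probes, and 0 probes were called in opposite directions. Across the tested probes, which are not independent replicates, the log2 changes of the 2 comparisons had a Pearson correlation of 0.64. The 1516 probes called in intact larvae gave each array a score, the mean log2 ratio of the rises minus that of the falls. In the amputated larvae, whose group means took no part in choosing them but whose arrays entered the shared estimate of the spread, the score was 0.70 ± 0.08 (SD, n = 4) in amp/beclo and -0.84 ± 0.05 in amp/veh (difference 1.54, two-sided exact permutation p = 0.0286). The 1914 probes called in amputated larvae separated con/beclo (0.62 ± 0.20) from con/veh (-0.76 ± 0.10) by 1.39 with the same exact p. The 364 probes called for amputation under beclomethasone separated amp/veh (0.80 ± 0.09) from con/veh (-0.05 ± 0.16) by 0.85, again with an exact permutation p of 0.0286. This is the smallest p that 70 splits of 4 against 4 can give, and all 3 tests of the family had it, so the Benjamini-Hochberg adjusted values are the same. These splits do not keep the same-numbered pairs, and with the pairs kept 4 slides are too few for a p under 0.05. The differences within slides ran from 1.37 to 1.67 for the first score, from 1.16 to 1.56 for the second and from 0.68 to 0.99 for the third, so each was above 0 on 4 of 4 slides. Single arrays of the third score ran from -0.19 to 0.17 in con/veh and from -1.31 to -0.48 in con/beclo. In amp/veh they ran from 0.67 to 0.87 and in amp/beclo from 0.79 to 1.30. So the intact groups lay apart while the amputated groups overlapped, though the choice of probes enters the beclomethasone groups.

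**Figure D4:**
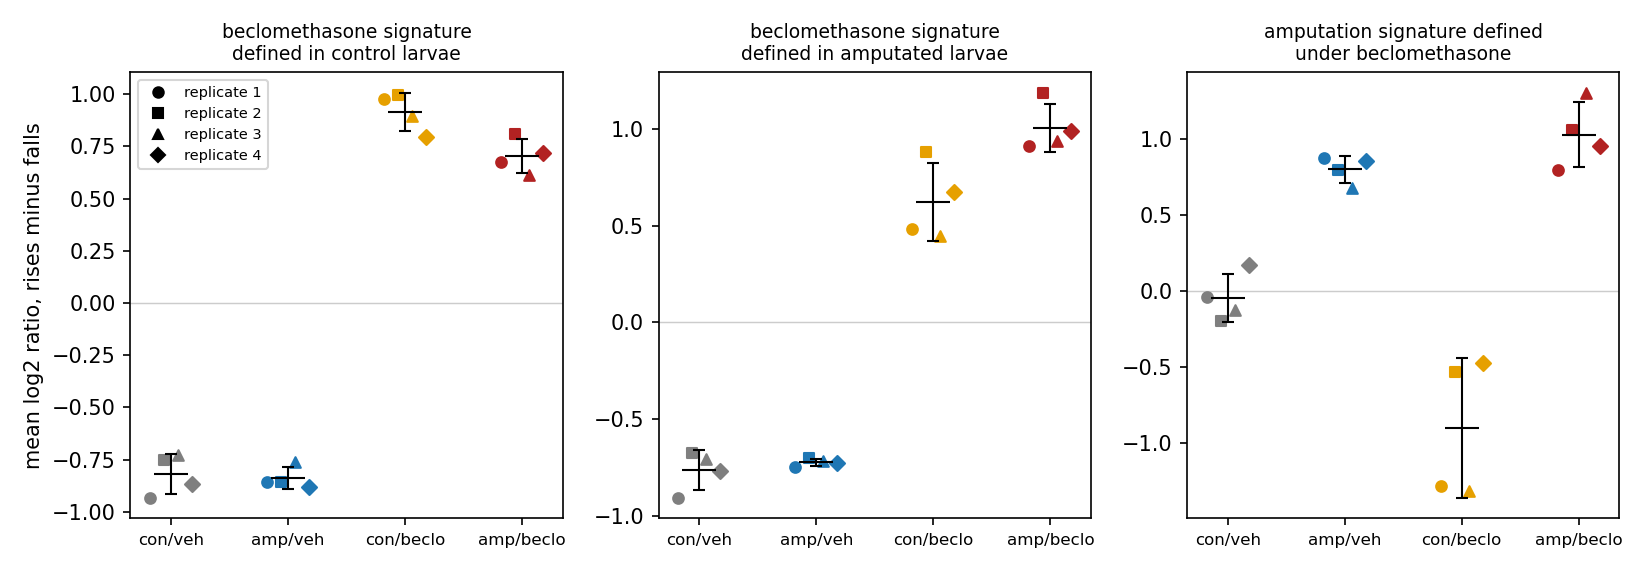
Scores of the 16 arrays (mean log2 ratio of the probes that rose minus that of the probes that fell) for the probes called for beclomethasone in intact larvae, for beclomethasone in amputated larvae and for amputation under beclomethasone, by group as labelled (symbols, replicates 1 to 4; line and bar, mean and SD, n = 4). The groups in which a score was defined are separated by construction, and the others entered the choice of probes through the filter and the shared estimate of the spread. The amputation score averaged -0.05 in con/veh and 0.80 in amp/veh.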

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

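The test of probe GC content was chosen only after the spread of amp/veh replicate 1 was seen. In each group of 4 arrays, the sample farthest from the others was set against the range of its group, for array measures, scores and named probes. Of 72 such sets of 4, 9 had a sample past the limit of Dixon's test, where chance gives about 1 in 20 (3.6 sets), and the measures are not independent of each other.

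The log2 ratios of amp/veh replicate 1 had an SD of 0.526, against 0.311 to 0.320 in the other 3 arrays of its group. With a smooth trend on probe GC content taken out of every array, the SD of its deviation from the group mean was 0.329 (0.357 before), above the 0.236 that no array other than it and amp/beclo replicate 3 exceeded, so GC content is not the whole cause. Its reference channel deviated from the mean of the 16 by an SD of 0.165, within the 0.131 to 0.172 of the other 15, which argues against a fault of the whole array in both channels. Its beclomethasone score was -0.86, within the -0.88 to -0.76 of the other amp/veh arrays and far from the amp/beclo mean of 0.70, which argues against a wrong drug label. A difference of that larval RNA or of its labelling reaction, technical or biological, stays open and was not tested.

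In con/veh replicate 3 the log2 ratios correlated with probe GC content at -0.129 across probes, against -0.00576 to -0.00341 in the other con/veh arrays. The remaining 7 values are of probes named in the results, and LOL02517 was far out in 2 groups. In amp/veh, LOL02517 had a log2 ratio of -1.37 in replicate 1 and -2.87 to -2.72 in the others, and in amp/beclo it had -0.52 in replicate 1 and -2.43 to -2.11 in the others. MAD_Dr_004_170500-1 stood at -0.20 in amp/beclo replicate 1 and at -2.33 to -2.01 in the others. MAD_Dr_004_176632-1 stood at -1.51 in amp/beclo replicate 3 and at -0.77 to -0.62 in the others, and MAD_Dr_004_158535-1 at 0.52 in the same array and at 0.83 to 0.88 in the others. LOL04917 had -0.77 in con/veh replicate 2 and -1.37 to -1.29 in the others. A_15_P100902 had -2.62 in con/beclo replicate 2 and -1.64 to -1.45 in the others.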

How the results depend on the processing

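The removal of the GC trend, the arrays that stood apart, the green channel alone, 1 probe per overlap group and red as the sample channel were tried only after the data were seen. No named probe turned its direction under any alternative except red as the sample channel, which turns every sign. The direction with more probes did turn for beclomethasone in intact larvae (605 rises, 911 falls): to 810 and 687 with median centring, 725 and 720 without con/beclo replicate 4, and 3742 and 3339 with the replicate block and without the arrays that stood apart. The interaction stayed at 0 probes in all 19 settings that kept all arrays or left out the pair that stood apart, and was 1 without con/beclo replicate 4. With the replicate block, 3156 probes were called for beclomethasone in intact larvae, 1265 for amputation under beclomethasone and 3407 for beclomethasone in amputated larvae, with 1815 shared by the 2 beclomethasone comparisons, and the block left the other counts at 1, though of another probe, and 0. The experiment code as block gave 2449 for beclomethasone in intact larvae and 1457 for amputation under beclomethasone, and a random block gave 2964, 1214, 2998 and 1671 in the order of the replicate block. Array quality weights with robust spread gave 3578, 1098, 3448 and 1782 in that order and 4 for amputation in vehicle. A change of at least 2-fold, which asks for more, left 392, 178, 637 and 282.

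The scanner's processed signals and the authors' deposited table each called 0 probes for amputation in vehicle and 132 for amputation under beclomethasone, and median centring called 742 for the latter. Fits of the compared groups alone called 8 for amputation in vehicle, 0 for amputation under beclomethasone, 871 for beclomethasone in amputated larvae and 559 shared, so the share of amputation calls in vehicle found again under beclomethasone was 0%, against 100% (1 of 1). The GC correction gave 216 for amputation under beclomethasone. With the replicate block as well, it gave 5 for amputation in vehicle, 3901 for beclomethasone in intact larvae, 903 for amputation under beclomethasone, 3874 for beclomethasone in amputated larvae and 2227 shared. Without amp/veh replicate 1 and amp/beclo replicate 3, 3069 were called for beclomethasone in intact larvae and 205 for amputation under beclomethasone. With the replicate block these arrays left out gave 10, 7081, 1177, 4025 and 2711 in the order of the sentence on GC and block. The green channel alone gave 0 for amputation in vehicle and 242 for amputation under beclomethasone. The cause of these moves was not tested.

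Leaving out 1 array or 1 slide gave 0 to 1 probes for amputation in vehicle, 258 to 2572 for beclomethasone in intact larvae, 3 to 1094 for amputation under beclomethasone, 537 to 2826 for beclomethasone in amputated larvae, 0 to 1 for the interaction and 196 to 1387 shared, with fewer arrays in each fit, and the share of amputation calls stayed at 100% where it had a value. For amputation under beclomethasone, the count was 48, 733, 77 and 871 without con/beclo replicates 1 to 4, 64 and 87 without amp/beclo replicates 2 and 3, 1094, 229 and 235 without amp/veh replicates 1, 2 and 4, and 233 and 229 without con/veh replicates 2 and 3. For beclomethasone in intact larvae it was 782, 850, 916 and 744 without con/veh replicates 1 to 4, 879 and 948 without con/beclo replicates 1 and 2, and 2572 without amp/veh replicate 1. For beclomethasone in amputated larvae it was 1275 without amp/veh replicate 2 and 1095 without amp/beclo replicate 2. Of the values of the named probes under the alternatives fixed beforehand, 328 of 429 kept their side of the threshold and 101 lost it. For amputation under beclomethasone, MAD_Dr_004_640980-1 lost it without con/beclo replicate 1 (adjusted p 0.0791) or 3 (0.0778) or amp/beclo replicate 2 (0.0617), LOLS15693 without con/beclo replicate 1 (0.067) or 3 (0.0663), and LOL04917 without con/beclo replicate 1 (0.0515) or amp/beclo replicate 2 (0.0505). There MAD_Dr_004_170500-1 lost it without the same single arrays as for its rise (up to 0.151). In the 100-probe cross-fit, the change under beclomethasone was 1.19 to 2.84 times that in vehicle for probes selected in vehicle and 1.90 to 3.45 times for those selected under beclomethasone. The brightest probe of a gene and the gene lists were not run, since no probe has a gene name. Signal limits little here, as 132910 probes were above background on all 16 arrays.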

Other observations

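The test of the channels by the mixed reference was chosen only after the results were seen. So were, for the amputation counts, the tests of the spread of amp/veh replicate 1, of GC content and of mirrored labels. The cross-fit was set before its own result was seen, but its choice of 100 probes was added after other results were.

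Probes on opposite strands of the same sequence moved together less than probes of the same strand. Over 3650 opposite-strand pairs the log2 changes correlated at 0.34 for amputation in vehicle, 0.63 for beclomethasone in intact larvae, 0.49 for amputation under beclomethasone and 0.67 for beclomethasone in amputated larvae, across probe pairs, against 0.85 to 0.94 for same-strand pairs. In 20 pairs both strands were called the same way for beclomethasone in intact larvae and in 27 for beclomethasone in amputated larvae, with 0 pairs called in opposite directions. The hypothesis that the altered transcripts carry AU-rich elements, which mark unstable messages, was tested by the share of probes with an ATTTA. It was 10.4% of the 299 groups that changed after amputation under beclomethasone, against 11.5% in random sets matched on GC content (percentile 23.8). It was 8.05% of the 1243 groups that fell with beclomethasone in amputated larvae, against 8.65% (percentile 20.3). Neither set was enriched, though a 60-base probe covers little of a transcript. Only the strand of the probe as given was searched, and the array holds probes of both strands. Elements of transcripts that read from the other strand may have been missed.

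The red channel, which the labels give to the larval samples, hardly differed between arrays, and a fit of it alone called 0 probes in every comparison (limma), with 2201 to 3602 at an unadjusted p under 0.05. A compressed or saturated red channel was argued against by its SD of log2 signal across probes, which was 98.0% of that in green, with 0% of spots saturated. Over the 1000 most variable probes the mean green over red had a median log2 of 0.0566, and the mean red over green had 0.60, which is consistent with larval samples in green and the mixed reference in red. No biological explanation was tested.

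More probes were called for amputation under beclomethasone (364) than in vehicle (1) with 1 spread estimated from all 16 arrays, but the order turned, to 0 and 8, when each pair of groups was fitted alone. LOL04917, for example, had an SD of 0.28 in con/veh and 0.23 in amp/veh, but 1.07 in con/beclo and 1.17 in amp/beclo. Whether an unequal spread of the groups made the order turn was not tested. Without amp/veh replicate 1 the counts were 0 in vehicle and 1094 under beclomethasone, which goes against its wide spread as the cause. The test is a weak one, because it leaves fewer arrays in amp/veh, and leaving out any other amp/veh array also gave 0 in vehicle. With the GC trend taken out the counts were 1 and 216, which argues against GC content as the whole cause. The count under beclomethasone fell from 364, so a part of GC content in it stays open. The log2 ratios correlated with probe GC content between -0.161 and -0.0339 in the con/beclo arrays. In the amp/beclo arrays these correlations lay between -0.0309 and 0.261. A larger change under beclomethasone went with the unused replicates, where it was 2.37 times the change in vehicle (1.59 to 3.19) for probes selected under beclomethasone and 1.87 times for probes selected in vehicle (1.40 without amp/veh replicate 1, 1.26 without amp/beclo replicate 3 as well, and 1.19 with the replicate block added), although the interaction passed the threshold for 0 probes. Mirrored group labels, con/veh for amp/beclo and amp/veh for con/beclo on every slide, could also give this pattern, since the same values would then read as a larger response to amputation in vehicle, made mostly of rises. The 2 cannot be told apart here, because the test needs transcripts of known response and 0 probes have a gene name.

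Other splits of the arrays were set against the real ones, in all 35 splits of the 8 arrays of a comparison. For beclomethasone in intact larvae, 1 of 35 splits, the real one, gave as many as 1516 probes and the highest other gave 0, and for amputation under beclomethasone 1 of 35 gave 364 and the highest other, with con/beclo replicate 2 and amp/beclo replicate 4 exchanged, gave 184. For both, 1 of 35 is the smallest share that these splits can give, and it was not adjusted over the 4 comparisons. The splits also do not keep the pairs, so they argue against chance without excluding it. For amputation under beclomethasone, a fit of the con/beclo and amp/beclo arrays alone called 0. For beclomethasone in amputated larvae 2 of 35 splits gave as many as 1914, and the other, with amp/veh replicate 1 and amp/beclo replicate 4 exchanged, gave 4004, so this count alone did not exclude chance. Other values argue against chance there: the probes called in intact larvae separated amp/beclo (0.70 ± 0.08) from amp/veh (-0.84 ± 0.05) on 4 of 4 slides, and 258 rises and 734 falls were shared with intact larvae, against 1.94 and 9.10 for independent lists. For amputation in vehicle 2 of 35 splits gave at least 1 probe, with a highest other of 1, so this count alone did not exclude chance. For the 364 probes called for amputation under beclomethasone, taken as a set, other values argue against chance. They separated amp/veh (0.80 ± 0.09) from con/veh (-0.05 ± 0.16) on 4 of 4 slides, and 98.9% of their 349 falls went the same way in vehicle. Probes are not independent replicates, so this share is no count of separate agreements. Across all tested probes the changes of the 2 amputation comparisons had a Pearson correlation of 0.59. Without amp/veh replicate 1 and amp/beclo replicate 3 it was 0.32. In each of the 4 comparisons, the 7 other splits that part all 4 same-numbered pairs called 0 probes, but 8 such splits are too few for a share under 1 in 20, so with the pairs kept the splits decide nothing on chance. For the interaction, all 100 drawn splits of the 16 arrays gave at least the real 0, as any split must, with a highest other of 363, so this count decides nothing.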
